A study of Ovis aries with 8 samples.

How the data were processed

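Poly-A RNA of fresh longissimus thoracis, the loin muscle over the ribs, was sequenced from 8 castrated crossbred lambs (Ovis aries), 4 on a control diet (CON) and 4 on a diet with 20% soybean molasses (SM20). Per the series' design text, the lambs came from a feeding trial of 20 animals, 10 per diet, and the 4 sequenced per diet were drawn at random. Soybean molasses is a sugar-rich co-product of soy protein concentrate. RNA was extracted with RNeasy Mini columns and libraries were prepared with the TruSeq Stranded mRNA kit, per the labels' protocols. The 4 replicates of a diet are separate lambs.

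The deposited table holds whole-number read counts per gene symbol for the 8 libraries, with no normalization by the authors. Per the submitters' processing notes, the reads passed through Trim Galore, cutadapt, STAR, featureCounts and DESeq2. The versions, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. Without the strand setting, it is not known whether the counting told reads of overlapping and antisense genes apart. Genes with near-identical copies, such as ribosomal protein genes with processed pseudogenes and mitochondrial genes with nuclear copies, carry an uncertainty of read assignment. The table holds 11247 genes and has no gene with 0 counts in every library. Some abundant muscle genes are not in it and were not analysed here, so library totals are totals over the listed genes. No coordinates are printed because the build is not stated. Of the symbols, 10761 matched a symbol or synonym of the RefSeq annotation of ARS-UI_Ramb_v3.0, which was used for that check only. A deposited sample sheet gave the same diet as the labels for all 8 libraries, and every column matched 1 sample by its library name.

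Total counts per library ranged from 8675527 to 11210065. Spread between lambs limits the precision, and genes under about 1 CPM also rest on few reads. The common biological coefficient of variation was 0.225 and the median standard error of a log2 fold change was 0.20. The counts of every pair of libraries differed by far more than sampling noise, with a chi-square of at least 21.6 per degree of freedom, so each library was treated as a separate lamb. The labels name 1 lamb per library, and replicate numbers here follow accession order and pair nothing.

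Differences between diets were tested with the quasi-likelihood F-test of edgeR (version 4.0.16, R 4.3.3), with the diet as the only term, TMM scaling factors and the default expression filter of edgeR, with a minimum count of 10, which kept 9779 genes. The 1468 genes left out held 0.0735% of the counts. P-values are two-sided and were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are TMM-scaled counts relative to library size (CPM), given as mean ± SD over the 4 lambs of a diet.

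A set of 32 gene lists was fixed before the data were examined, covering lipid, energy, antioxidant and fibre-type genes, markers of other cell types, and stress and RNA-quality genes. The 30 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2. The preset correlation between genes was 0.01, and p-values were adjusted over the lists. Camera was repeated with a correlation estimated for each list, and fry was run beside it. Fry asks whether the genes of a list move on balance one way, or in either direction, without comparing them with other genes. The lymphocyte list had 4 tested members and the erythrocyte list 1, and neither was tested. An exact two-sided permutation test of each list's mean log2 CPM per lamb was added after the data were seen. With 4 lambs against 4, there are 70 assignments and the smallest p is 0.0286.

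The test, the first set of other settings named below and a rule for the genes to be named were set at the same time as the lists. The rule takes up to 12 genes per direction past the threshold with a mean of at least 1 CPM. Where fewer than 6 passed in a direction, it adds the 6 with the smallest p that missed the threshold and whose diets did not overlap. From each list it takes up to 4 members past the threshold, or otherwise the 2 members with the smallest p, and the genes past 0.05 when adjusted over the list alone. Some genes that the rule takes are not reported here.

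The test was tried on simulated counts for the comparison of SM20 with CON, drawn for 9779 genes from the real means, dispersions and library sizes, of which 9684 passed the filter. Of the genes changed 3-fold, 92.1% were recovered, against 56.7% of those changed 2-fold and 16.4% of those changed 1.5-fold. Of 115 calls, 7 were unchanged genes. A simulated 1.3-fold shift of 1 list was called, and 0 of the other lists were. Genes were drawn independently, whereas the estimated correlation within the real lists reached 0.70. The simulation therefore does not show how often lists whose genes vary together are called falsely.

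Alternatives covered median-of-ratios and upper-quartile scaling, library size alone, other expression filters, DESeq2 (version 1.42.0), limma-voom with and without sample weights, robust edgeR dispersions and 1 surrogate variable (sva 3.50.0). Further ones left out the mitochondrially encoded genes or each library in turn, or changed the prior count and the statistic of the list test. Chosen after seeing the data were an adjusted p under 0.10, the slow-fibre level as a covariate, the exact permutation of list means, the count of respiratory subunits adjusted over their list alone under each setting, and 3 check lists (short messenger RNAs, long messenger RNAs and endothelial markers alone).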

Results

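Read counts were obtained for longissimus thoracis of 8 castrated lambs, 4 fed the control diet (CON) and 4 fed the diet with 20% soybean molasses (SM20). The comparison asks how the diet altered transcript levels in the muscle of a trial concerned with fat deposition and the oxidation of meat lipids. Total counts were 9994038, 11210065, 9476749 and 9291292 in CON lambs 1 to 4. They were 10305590, 10015964, 8675527 and 9926955 in SM20 lambs 1 to 4. Rank correlations across genes between libraries ran from 0.961 to 0.983. On the 500 most variable genes neither the first principal component (26.3% of the variance, exact permutation p = 0.571) nor the second (20.3%, exact permutation p = 0.486) separated the diets. CON lamb 1 had the most extreme score on the first component, at -21.4 against -8.65 to 9.75 in the other lambs. On all tested genes the first component (25.5% of the variance) did separate them, with exact permutation p = 0.0286, the smallest the design allows, and 0.314 after Benjamini-Hochberg adjustment over 11 measures.

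Between the diets 5 genes passed the threshold, 4 of them higher and 1 lower in SM20. *ZC3H12C*, a zinc-finger endoribonuclease, rose 2.32-fold from 11.0 ± 0.81 to 25.5 ± 5.36 CPM (SD, n = 4 per diet). *USF3*, a basic helix-loop-helix protein of the upstream stimulatory factor family, rose 1.95-fold from 22.2 ± 2.43 to 43.3 ± 5.14 CPM. *SECISBP2L*, a relative of the selenocysteine insertion factor SECISBP2, rose 1.76-fold from 23.3 ± 1.18 to 41.1 ± 2.76 CPM. *CACNA2D1*, an auxiliary subunit of the voltage-gated calcium channel, rose 1.75-fold from 151.0 ± 9.67 to 264.5 ± 22.9 CPM. *KANK3*, an ankyrin-repeat protein of vascular endothelium, fell 2.03-fold from 52.2 ± 6.03 to 25.7 ± 1.40 CPM. All 4 SM20 lambs lay on one side of all 4 CON lambs for each of the 5 genes. The log2 fold changes were 1.21 ± 0.17, 0.96 ± 0.14, 0.82 ± 0.11, 0.81 ± 0.12 and -1.02 ± 0.12 (SE) in that order, and each had an adjusted p of 0.0456 by the quasi-likelihood test of edgeR. The calls sat close to the threshold: leaving out any 1 of the 8 libraries left 0 genes past it, with smallest adjusted p-values between 0.0860 without CON lamb 2 and 0.202 without CON lamb 4. At those settings 1476 to 1876 genes still had an unadjusted p under 0.05.

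**Figure D1:**
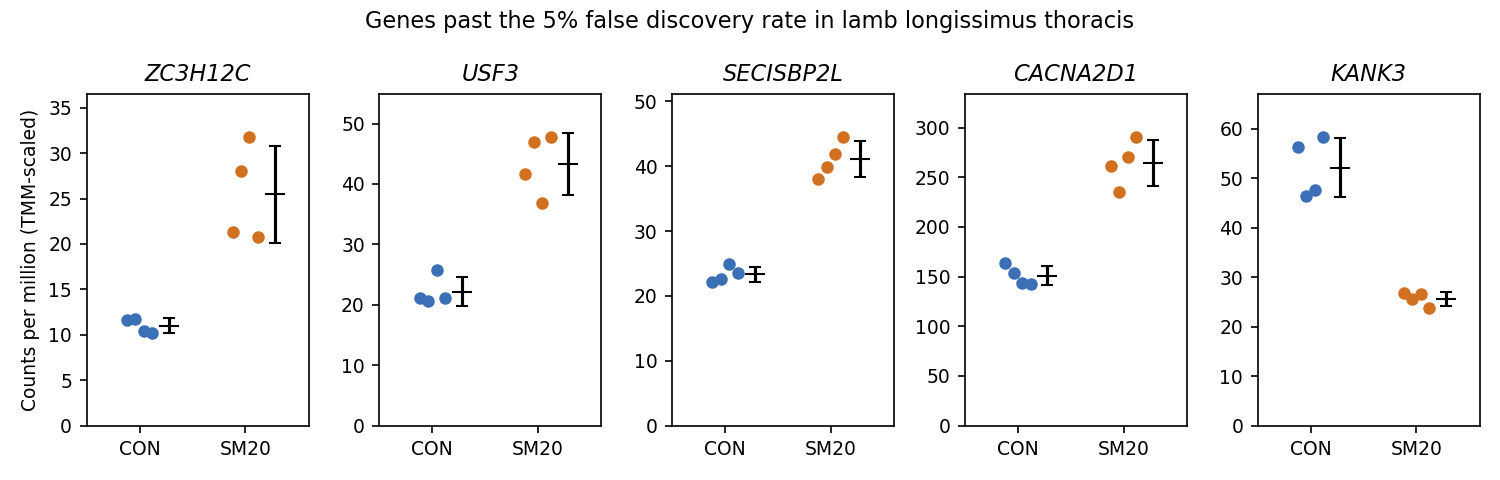
TMM-scaled CPM of the 5 genes past the threshold, 1 point per lamb on linear axes that start at 0, with the mean and SD of the 4 lambs of each diet in black. The SM20 lambs lie above all CON lambs for ZC3H12C, USF3, SECISBP2L and CACNA2D1 and below all of them for KANK3.

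Beyond these 5 genes, low p-values were frequent. Of the 9779 genes tested, 1788 had an unadjusted p under 0.05 against 489 by chance alone, 962 of them higher and 826 lower in SM20. The share of higher genes among them was 53.8% with TMM, 66.9% with library size alone and 43.6% with upper-quartile scaling, so the balance of higher and lower genes depends on the scaling. At an adjusted p under 0.10 there were 129 genes, 89 higher and 40 lower. DESeq2, which was run on the same counts, placed 446 genes past 0.05, 255 higher and 191 lower, and these included all 5 genes above. The diets did not overlap for 1194 genes, 12.2% of those tested, against 2.86% by chance.

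The genes nearest the threshold that missed it were named by the same rule. Higher in SM20 by log2 fold change were the deubiquitinases *USP13* (0.96 ± 0.14, SE) and *OTUD4* (0.68 ± 0.11), the secreted guidance factor *SEMA3C* (1.04 ± 0.17) and the sestrin *SESN3* (0.94 ± 0.16). So were *NF1* (0.72 ± 0.12), a negative regulator of Ras, and the RNA helicase *DDX6* (0.75 ± 0.13). Lower were *GAMT* (-1.02 ± 0.17), the last enzyme of creatine synthesis, *RNF207* (-1.22 ± 0.21), a RING-finger protein, and *GUK1* (-0.75 ± 0.13), guanylate kinase. The other lower genes were *NDUFS8* (-0.64 ± 0.12), a subunit of respiratory complex I, *NOTCH4* (-0.95 ± 0.17), an endothelial Notch receptor, and *ALDH4A1* (-0.77 ± 0.14), a mitochondrial enzyme of proline breakdown. Their adjusted p was 0.0607 for USP13 and 0.0764 for the other 11 by edgeR.

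All 39 tested members of the list of nuclear-encoded respiratory chain subunits had a negative log2 fold change, with a median of -0.45. The list does not hold every subunit: NDUFS8 is outside it, and complex II subunits were placed in the tricarboxylic acid cycle list. The list passed as lower by camera with the preset correlation (adjusted p = 5.2e-18) and not with an estimated correlation (adjusted p = 0.506). Over all genes 0 subunits passed the threshold by edgeR and 21 passed it as lower by DESeq2. When adjusted over the list alone 29 passed as lower by edgeR, which were 18 of 24 subunits of complex I, 5 of 6 of complex III, 2 of 2 of complex IV and 4 of 7 of complex V. *NDUFV1*, the NADH-binding subunit of complex I, averaged 538.0 ± 92.7 CPM in CON and 299.9 ± 46.9 CPM in SM20, a log2 fold change of -0.84 ± 0.16 (SE, n = 4 per diet). *NDUFA13* had -0.61 ± 0.13, *UQCRC1* of complex III -0.59 ± 0.14, *COX4I1* of complex IV -0.51 ± 0.14 and *ATP5F1D* of the ATP synthase -0.62 ± 0.13. The mean level of the list was lower in every SM20 lamb than in every CON lamb, with exact permutation p = 0.0286 before and 0.214 after adjustment over the 30 lists. Without CON lamb 1, which had the highest level, 38 of the 39 subunits had a negative fold change, the median was -0.34 and 22 passed when adjusted over the list alone. Short messenger RNAs from outside mitochondria and ribosomes, a list drawn up after the data were seen, had a median of -0.18, with 37 of 45 members negative and an exact permutation p of 0.0286 for the list mean.

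**Figure D2:**
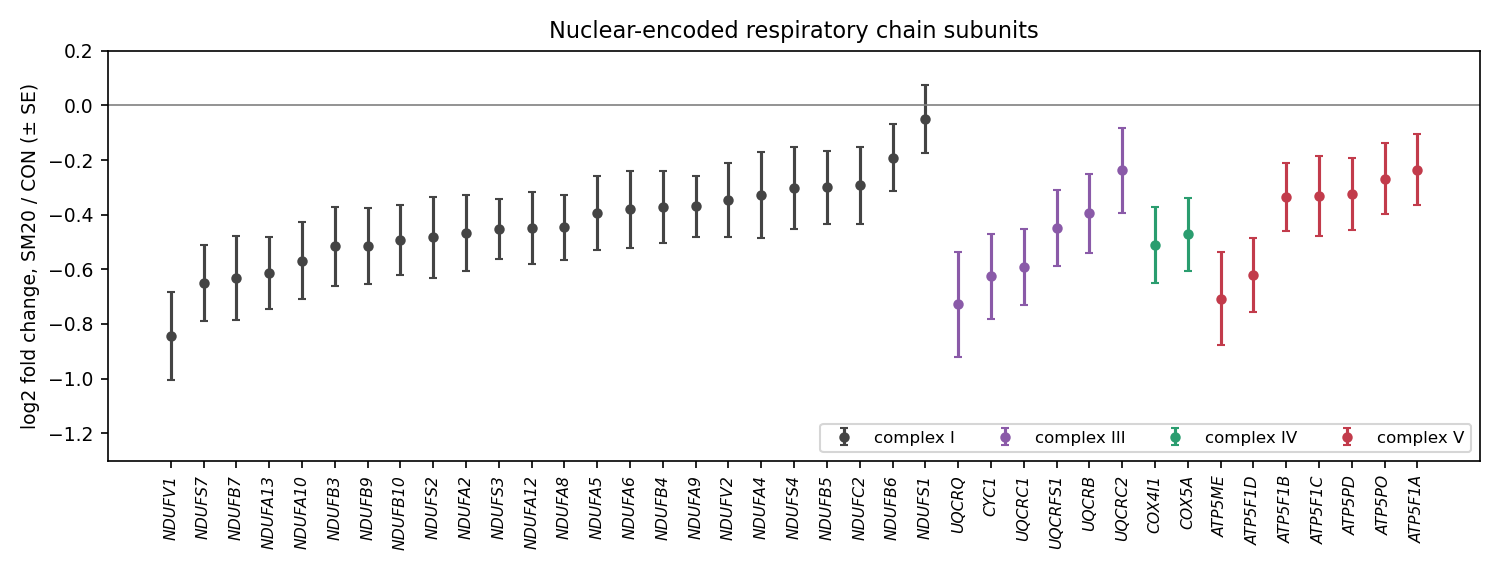
Log2 fold change of SM20 over CON with its standard error for the 39 tested members of the list of nuclear-encoded respiratory chain subunits, ordered by complex and by value. All 39 points lie below 0, from -0.84 for NDUFV1 to -0.05 for NDUFS1.

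The tricarboxylic acid cycle and pyruvate oxidation list had 18 of 23 members negative and a median log2 fold change of -0.30. Its adjusted p by camera, as lower, was 5.2e-04 with the preset and 0.556 with an estimated correlation. The short messenger RNAs from elsewhere in the cell, a list drawn up after the data were seen, were also lower (median -0.18, exact permutation p = 0.0286). The slow-fibre genes also had a negative median (-0.40), but as a list they did not pass (camera adjusted p = 0.111, exact permutation p = 0.429). CON lamb 1 had the highest level of both the tricarboxylic acid cycle and the slow-fibre list. When adjusted over the list alone 6 of its members passed, all lower: *IDH2* (-0.73 ± 0.15, SE), *IDH3G* (-0.58 ± 0.13), *IDH3B* (-0.54 ± 0.14), *MDH2* (-0.53 ± 0.13), *SUCLG1* (-0.46 ± 0.13) and *PDHB* (-0.34 ± 0.11). These encode subunits of isocitrate dehydrogenases, malate dehydrogenase, succinyl-CoA ligase and pyruvate dehydrogenase. Over all genes 0 passed by edgeR and 6 by DESeq2. The count of 6 when adjusted over the list alone became 4 without CON lamb 1 or CON lamb 4, 3 without SM20 lamb 2, 2 without SM20 lamb 3 and 9 without SM20 lamb 4.

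The 11 tested genes encoded by the mitochondrial genome all had negative fold changes, with a median of -0.41 that was -0.27 without CON lamb 2. The list passed as lower by camera with the preset correlation (adjusted p = 5.2e-04) and not with an estimated correlation (adjusted p = 0.556). Short messenger RNAs from elsewhere in the cell, a list drawn up after the data were seen, were also lower (median -0.18, exact permutation p = 0.0286). The slow-fibre genes also had a negative median (-0.40), but as a list they did not pass (camera adjusted p = 0.111, exact permutation p = 0.429). CON lambs 1 and 2 had the highest levels of both the mitochondrially encoded and the slow-fibre list. With the slow-fibre level as a covariate, a setting chosen after seeing the data, the median was -0.32 and 0 members passed when adjusted over the list alone. *COX3* (-0.67 ± 0.17, SE) and *COX1* (-0.58 ± 0.17), which encode core subunits of cytochrome oxidase, passed as lower when adjusted over the list alone, and over all genes 0 members passed by edgeR and 2 by DESeq2. The first count of 2 became 0 without CON lamb 1, CON lamb 2, SM20 lamb 1, SM20 lamb 3 or SM20 lamb 4, and 9 without CON lamb 4. Together these genes took 9.45 ± 1.41% of all counts in CON and 6.86 ± 0.90% in SM20, a difference of -2.59 percentage points (exact permutation p = 0.0571, adjusted p = 0.314 over the 11 measures). Without CON lamb 4 the difference was -3.21 points with exact permutation p = 0.0286. Leaving out any other single lamb gave an exact permutation p of 0.0571 to 0.0857.

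Of 39 subunits of the cytosolic ribosome, 38 had negative fold changes, with a median of -0.29, among them *RPL3* (-0.43 ± 0.12, SE) and *RPL28* (-0.47 ± 0.14). The list's adjusted p by camera, as lower, was 2.5e-09 with the preset and 0.556 with an estimated correlation. Short messenger RNAs from elsewhere in the cell moved with it, at the median of -0.18 and 37 of 45 negative given above. By edgeR 0 ribosomal genes passed over all genes or when adjusted over the list alone. On the second criterion 10 were lower with upper-quartile scaling and 4 with DESeq2, which placed 2 past the threshold over all genes.

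Among lipid genes the lists of synthesis, storage and uptake did not pass. The list of fatty acid synthesis and desaturation had 5 members higher and 11 lower (median -0.17, adjusted p = 0.146 by camera), and without CON lamb 3 the median was -0.02 with 9 of 16 negative. Its members with the smallest p were *THRSP*, a lipogenic regulator, at 8.43 ± 1.74 CPM in CON and 4.46 ± 1.98 CPM in SM20 (adjusted p = 0.180 by edgeR), and *ACACA*, acetyl-CoA carboxylase, with a log2 fold change of -0.41 ± 0.22 (SE) that was -0.20 without CON lamb 3. Triglyceride assembly and lipid droplet genes had a median of -0.26 (adjusted p = 0.227). In that list *GPAM*, which starts glycerolipid synthesis, had 0.72 ± 0.21 and the lipid droplet protein *PLIN5* -0.51 ± 0.18, or -0.32 without CON lamb 4. Fatty acid uptake and lipolysis genes had a median of -0.24 (adjusted p = 0.451), which was closest to 0 without CON lamb 4 at -0.11, with *PNPLA2*, the first lipase of triglyceride breakdown, at -0.48 ± 0.17 and the fatty acid transporter *SLC27A1* at -0.50 ± 0.20. By edgeR with all 8 libraries 0 members of these 3 lists passed over all genes or when adjusted over the list alone. On the second criterion 1 uptake and lipolysis gene was lower without CON lamb 2. In the triglyceride list 1 was higher with DESeq2 and 1 lower with the slow-fibre level as a covariate, a setting chosen after seeing the data. DESeq2 also called GPAM over all genes (adjusted p = 0.0448).

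For mitochondrial fatty acid oxidation, 17 of 24 members were negative (median -0.12, camera adjusted p = 0.1002). Adjusted over the list alone 4 were lower: *ECHS1* (-0.57 ± 0.14, SE), *ETFB* (-0.56 ± 0.14), *ECI1* (-0.51 ± 0.14) and *HADH* (-0.37 ± 0.11). This count of lower members was 0 without CON lamb 1, CON lamb 3, SM20 lamb 1 or SM20 lamb 3, and 1 without SM20 lamb 2. It was 3 without CON lamb 2 and 2 without CON lamb 4, each beside 1 higher member, and 4 beside 2 higher members without SM20 lamb 4. Over all genes 0 passed by edgeR and 4 by DESeq2. The peroxisomal list had a median of -0.01 (adjusted p = 0.684). In it *ACOX2*, the branched-chain acyl-CoA oxidase, was lower when adjusted over the list alone (2.11 ± 0.35 CPM in CON, 0.50 ± 0.35 CPM in SM20), where the SM20 level rests on few reads per library. The cholesterol list had a median of -0.09 (adjusted p = 0.439). *STARD4*, a sterol transporter, was higher (0.92 ± 0.22) and *MVK*, mevalonate kinase, lower (-0.82 ± 0.22) when adjusted over the list alone. The count of 2 fell to 0 without any 1 of the 4 CON lambs or SM20 lamb 3, and to 1 without SM20 lamb 1. Over all genes 0 members of the peroxisomal and cholesterol lists passed by edgeR or DESeq2. The edgeR adjusted p was 0.0871 for ACOX2, 0.107 for STARD4 and 0.115 for MVK.

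Of 31 antioxidant genes 23 were negative, with a median of -0.12. The list passed as lower by camera with the preset correlation (adjusted p = 0.0293) and not with an estimated correlation (adjusted p = 0.506). The list of short messenger RNAs had a median further below 0, at -0.18 with 37 of 45 negative. When adjusted over the list alone 4 members were lower: *TXNRD2* (-0.65 ± 0.12, SE) and *PRDX5* (-0.54 ± 0.12), a thioredoxin reductase and a peroxiredoxin of mitochondria, the cytosolic peroxiredoxin *PRDX2* (-0.56 ± 0.16) and the muscle selenoprotein *SELENOW* (-0.51 ± 0.14). On that criterion 0 members were higher, and over all genes 0 passed by edgeR and 4 by DESeq2. The list's adjusted p by camera was 0.118 without SM20 lamb 3, where its median was -0.08, within a range over the alternatives of 0.00888 to 0.506. The count of 4 became 2 without CON lamb 1, CON lamb 4, SM20 lamb 1, SM20 lamb 2 or SM20 lamb 3. Glutathione transferases and aldehyde-clearing enzymes had a median of -0.19 (adjusted p = 0.142), with *GSTK1*, a glutathione transferase of mitochondria and peroxisomes, lower when adjusted over the list alone (-0.74 ± 0.18) and *ALDH2* at -0.36 ± 0.14. On that criterion 0 members passed without CON lamb 1, CON lamb 3, SM20 lamb 1 or SM20 lamb 2, and 2 without SM20 lamb 4. Over all genes edgeR called 0 members of that list and DESeq2 called 1 as lower.

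Genes of sugar metabolism and growth did not pass as lists. Glycolysis and glycogen genes had a median of -0.07 (camera adjusted p = 0.676). *HK2*, hexokinase of muscle, had 1.02 ± 0.39 (SE), or 0.60 without SM20 lamb 1. Insulin signalling and glucose uptake genes had 17 of 21 members positive (median 0.16, adjusted p = 0.111). *PRKAA2*, the catalytic AMP-activated kinase subunit of muscle, was higher when adjusted over the list alone, at 93.0 ± 12.4 CPM in CON and 147.6 ± 22.1 CPM in SM20, and *PIK3CA* had 0.51 ± 0.17. On that criterion 0 members passed without CON lamb 4, 2 without CON lamb 1 and 3 without SM20 lamb 4, and the list itself passed by camera without SM20 lamb 3 (adjusted p = 0.0376, range over the alternatives 0.0376 to 0.506). Muscle growth and satellite cell genes had a median of 0.21 (adjusted p = 0.146), with *IGF1R* at 0.61 ± 0.16 and *IGF1* at 0.89 ± 0.33. No growth gene passed when adjusted over the list alone, against 1 without CON lamb 4 and 2 without SM20 lamb 2. For muscle protein breakdown the median was 0.00 (adjusted p = 0.816), with *FBXO30* at 0.51 ± 0.20 and *GABARAPL1* at -0.47 ± 0.16. In the calpain and tenderness list (median -0.00, mean 0.07, adjusted p = 0.439), the giant thin-filament protein gene *NEB* was higher when adjusted over the list alone (0.65 ± 0.14), and *CAST*, the calpain inhibitor calpastatin, had 0.41 ± 0.14. NEB also passed over all genes with DESeq2 (adjusted p = 5.3e-04) and with library size alone, and not by edgeR with TMM (0.0873). Without CON lamb 2, 2 members of that list passed when adjusted over the list alone. Over all genes DESeq2 also called 1 member higher in each of the glycolysis, insulin signalling and growth lists. By edgeR 0 members of those lists passed over all genes, with an adjusted p of 0.0895 for PRKAA2. The test of the calpain list pointed up, as its mean did, while its median lay just below 0.

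Fibre-type genes and markers of other cell types were examined because they show what the muscle pieces held. Slow-fibre genes had a median of -0.40 without passing (camera adjusted p = 0.111). Without CON lamb 1 the median was -0.15 and 9 of 15 were negative. Slow troponin *TNNI1* averaged 542.5 ± 197.0 CPM in CON and 345.7 ± 101.7 CPM in SM20, and *TNNT1* had -0.56 ± 0.23 (SE). Without CON lamb 1 their log2 fold changes were -0.38 and -0.29. CON lambs 1 and 2 had the highest slow-fibre levels of the 8 lambs. The slow-fibre list passed as lower without CON lamb 3 (adjusted p = 0.0207), CON lamb 4 (0.00359, with 5 members past 0.05 when adjusted over the list alone) or SM20 lamb 1 (0.0483), and with library size alone (0.0404), within a range over the alternatives of 0.00359 to 0.821. Fast-fibre genes had a median of -0.15 (adjusted p = 0.142), with *TNNC2* at -0.36 ± 0.14 and *PGAM2* at -0.42 ± 0.17. Without CON lamb 1 the median was -0.05 with 8 of 14 negative and PGAM2 was at -0.24. The fast-fibre list passed as lower without CON lamb 3 (adjusted p = 0.00307, range 0.00307 to 0.851). Adipocyte markers varied widely within each diet, and 10 of 11 were negative with a median of -0.19 (adjusted p = 0.451, exact permutation p of the list mean 0.714). The adipocyte median was -0.01 without CON lamb 3 or SM20 lamb 4. *LPL*, lipoprotein lipase, had 59.2 ± 18.0 CPM in CON and 41.7 ± 12.8 CPM in SM20, a log2 fold change of -0.51 that was -0.33 without SM20 lamb 4. The medians were -0.07 for extracellular matrix and fibroblast genes (adjusted p = 0.342), 0.09 for macrophage markers (0.723), 0.07 for nerve and Schwann cell markers (0.676) and -0.04 for cell cycle genes (0.662). The members of these lists with the smallest p included *TIMP1* (-0.54 ± 0.18) and *POSTN* (-0.99 ± 0.36), *CTSS* (0.44 ± 0.37) and *C1QB* (0.44 ± 0.41), *L1CAM* (0.33 ± 0.34), and *PLK1* (-0.87 ± 0.50) and *RRM1* (0.20 ± 0.13), in that order. The extracellular matrix list passed as lower without SM20 lamb 1 (adjusted p = 0.00158, range over the alternatives 0.00158 to 0.958). Without SM20 lamb 4 C1QB turned to -0.13, CTSS was at 0.06 and RRM1 at 0.11. L1CAM was at 0.11 without CON lamb 1 and PLK1 at -0.45 without CON lamb 4.

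Of 21 endothelial and pericyte markers 17 were negative, with a median of -0.25. The list passed as lower by camera with the preset correlation (adjusted p = 0.0293) and not with an estimated correlation (adjusted p = 0.683). Over all genes 0 members passed by edgeR and 2, both lower, by DESeq2. Short messenger RNAs from elsewhere in the cell, a list drawn up after the data were seen, were also lower (median -0.18). The transcript lengths of the endothelial and pericyte markers were not examined. *EGFL7*, secreted by endothelial cells, averaged 69.3 ± 21.6 CPM in CON and 38.8 ± 6.17 CPM in SM20 and passed when adjusted over the list alone. *ROBO4*, an endothelial receptor, had -0.49 ± 0.15 (SE). *KDR*, the main receptor for vascular endothelial growth factor, was picked after its value was seen and had 0.43 ± 0.17. The list's adjusted p was 0.0837 without CON lamb 1, 0.0503 without CON lamb 4, 0.117 without SM20 lamb 2 and 0.120 without SM20 lamb 4, within a range over the alternatives of 5.8e-04 to 0.683. The count of 1 lower member when adjusted over the list alone became 0 without CON lamb 1, CON lamb 4, SM20 lamb 3 or SM20 lamb 4, and 3 without CON lamb 2 or SM20 lamb 1. Without SM20 lamb 2 it was 0 lower and 1 higher.

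Of 13 interferon response genes 11 were positive, with a median of 0.74. This was the single list to pass as higher by camera with the preset correlation (adjusted p = 0.0313), and it did not pass with an estimated correlation (adjusted p = 0.821). *IFI44*, an interferon-induced protein, averaged 0.64 ± 0.11 CPM in CON, a level that rests on few reads per library, and 2.12 ± 1.302 CPM in SM20. IFI44 passed when adjusted over the list alone, and *IFIT5* had 0.74 ± 0.23 (SE). SM20 lamb 4 had the highest level of the list and SM20 lamb 2 lay below 3 of the 4 CON lambs. The list's adjusted p by camera was 0.275 without SM20 lamb 4, where the median was 0.31, 0.0900 without SM20 lamb 1, and 0.0551, 0.0677 and 0.0786 without CON lambs 2, 3 and 4, within a range over the alternatives of 7.2e-05 to 0.821. The count of 1 when adjusted over the list alone became 6 without SM20 lamb 2, 5 without SM20 lamb 3 and 0 without any other lamb. Over all genes 0 members passed by edgeR or DESeq2, and the edgeR adjusted p was 0.113 for IFI44.

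Stress and clock genes did not pass as lists. Immediate early genes were spread within the diets (median -0.04, mean 0.22, camera adjusted p = 0.795), with *FOS* at 9.90 ± 6.36 CPM in CON and 93.8 ± 135.2 CPM in SM20 and *CCN2* at 1.02 ± 0.36 (log2 fold change, SE). SM20 lamb 2 had 294.2 CPM of FOS and the other SM20 lambs 5.16 to 54.9 CPM. Without that lamb the log2 fold change fell from 3.24 to 1.44 for FOS and to 0.65 for CCN2. Heat shock genes had a median of -0.03 (0.795), with *DNAJB1* at 0.59 ± 0.22 and *HSPB6* at -0.34 ± 0.19. DNAJB1 was at 0.35 without SM20 lamb 3, and HSPB6 at -0.22 without CON lamb 1 and -0.21 without SM20 lamb 4. The heat shock list passed as higher without CON lamb 2 (adjusted p = 0.0494, range over the alternatives 0.0494 to 0.956). For the heat shock and immediate early lists the test pointed up while the median was below 0, and for the circadian list the test pointed down while the median was above 0. Endoplasmic reticulum stress genes had a median of -0.06 (0.795), with the chaperone *CANX* at 0.34 ± 0.11 and *DNAJC3* at 0.44 ± 0.16. In the circadian list (median 0.04, mean -0.11, adjusted p = 0.942), *CLOCK*, an activator of the clock, was higher (0.80 ± 0.22) and *PER1*, a repressor, lower (-0.96 ± 0.26) when adjusted over the list alone. On that criterion 0 clock genes passed without CON lamb 1, CON lamb 4, SM20 lamb 3 or SM20 lamb 4, and 1 without CON lamb 3 or SM20 lamb 1. Over all genes edgeR called 0 clock genes, with an adjusted p of 0.117 for CLOCK and 0.117 for PER1, and DESeq2 called 1 higher and 1 lower. PER1 levels overlapped between the diets. Of the immediate early genes 0 passed when adjusted over the list alone, against 4 without SM20 lamb 4 and 1 without SM20 lamb 1. The medians of the heat shock, immediate early, calpain and peroxisomal lists turned positive with library size alone, and that of muscle protein breakdown turned negative with median-of-ratios and upper-quartile scaling. Across the 30 lists, camera with the preset correlation passed 7 (1 higher and 6 lower), and 0 passed with an estimated correlation. The directional fry test passed 0 lists, and its test for change in either direction passed 6: respiratory chain subunits, tricarboxylic acid cycle, antioxidant defence, cholesterol, mitochondrial fatty acid oxidation and peroxisomal fatty acid oxidation.

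**Figure D3:**
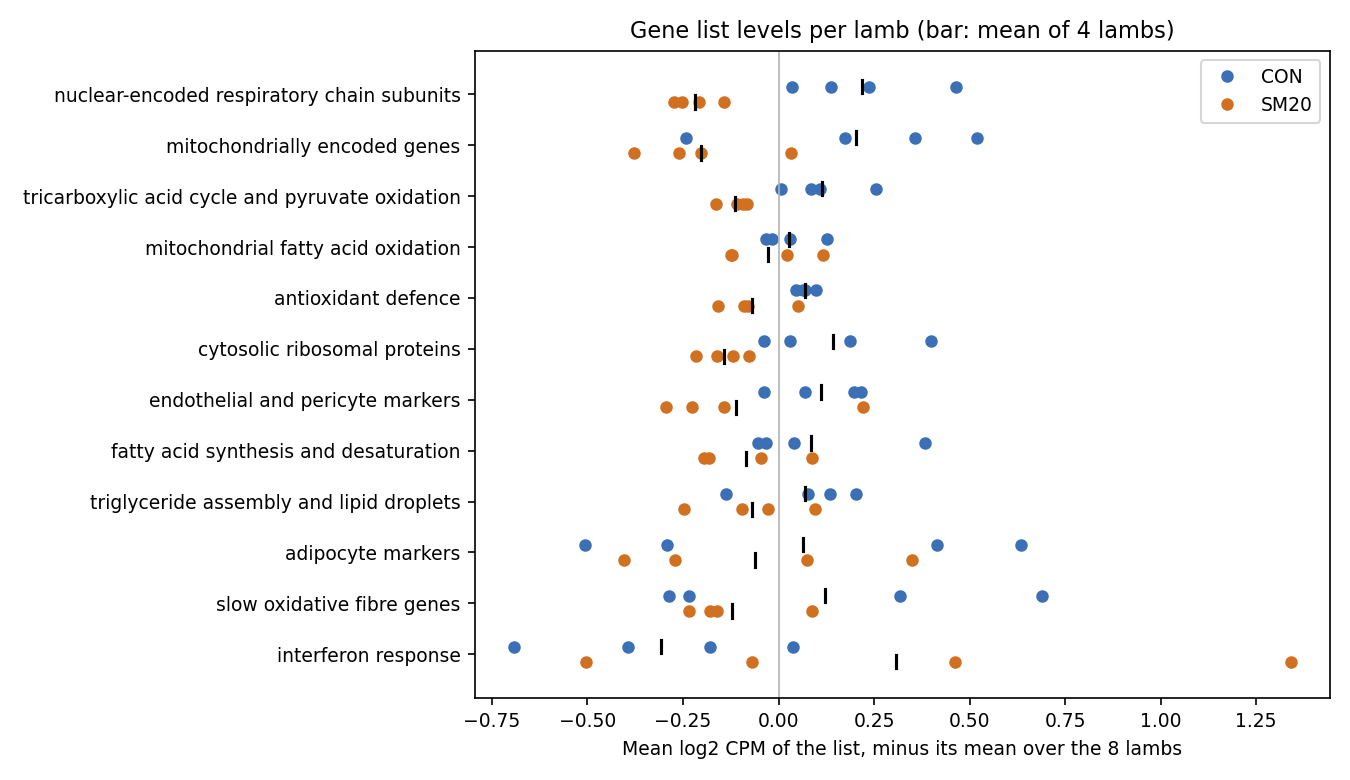
Mean log2 CPM of 12 gene lists per lamb, centred on the mean of the 8 lambs, with 1 point per lamb (blue CON, orange SM20) and a bar for the mean of each diet. The diets do not overlap for the respiratory chain subunits, the tricarboxylic acid cycle and the ribosomal proteins, and overlap for the other 9 lists.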

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

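Leaving out single libraries was set before the data were seen, and the other tests of an explanation here, including the splits of the lambs, were chosen after the results were seen. Among 294 groups of 4 lambs examined, 7 held a lamb whose gap to its nearest neighbour was a larger share of the group's range than Dixon's critical value, against 14.7 expected by chance. SM20 lamb 4 lay apart from the other SM20 lambs on the second principal component (gap share 0.903, at 9.90 against a nearest value of -6.36) and was low for NDUFB7 (0.844, log2 CPM 6.38 against 6.80). CON lamb 2 was high for the mean of the calpain and tenderness list (0.861, 9.05 against 8.50), CON lamb 3 for USF3 (0.884, 4.70 against 4.42) and CON lamb 1 for ETFB (0.863, 7.37 against 6.93). SM20 lamb 2 was high for ALDH2 (0.872, 10.58 against 10.29) and CON lamb 4 low for LPL (0.891, 5.03 against 6.04).

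The 8 lambs can be split into 4 and 4 in 35 ways. The diet split gave 5 genes past the threshold and the highest other split 4, so 1 of the 35 splits reached that count. For genes with an unadjusted p under 0.05 it gave 1788 and the highest other 978, again 1 of 35. The share of 1 in 35 (0.0286) is the smallest this test can give, and the splits were chosen after the results were seen. For the second count this speaks against chance without excluding it, and for the first the margin was 1 gene. The splits were not run under the alternatives, where the diet count was often 0 or 1. For lists past the threshold by camera with the preset correlation, 24 of the 35 splits gave at least the 7 of the diet split. The highest other gave 14, so such a count was common among the splits.

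The lower level of the respiratory chain subunits in SM20 was weighed against 3 technical or compositional explanations. Without CON lamb 1, which had the highest level, the median log2 fold change was -0.34 and the diets still did not overlap (exact permutation p = 0.0286), which argues against that lamb as the whole cause. With the slow-fibre level as a covariate the median was -0.39 against -0.45 without it (median SE 0.14). Of 39 subunits 22 still passed when adjusted over the list alone. The subunits vary together (estimated correlation 0.56), so their count is not separate evidence. All 4 SM20 lambs had respiratory levels below those of CON lambs 3 and 4. Their slow-fibre levels were above those of the same CON lambs, although SM20 lamb 2 was all but level with CON lamb 3 (9.321 against 9.320). These levels argue against fewer slow fibres as the whole cause, and a partial contribution may remain (exact permutation p = 0.0571 for the residual level). Relative to short messenger RNAs from elsewhere in the cell the respiratory level was lower by a difference of -0.25 (exact permutation p = 0.0571), so a lower reading of short messenger RNAs stays open, as does a response of the muscle to the diet.

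Endothelial markers passed as lower as a list with the preset correlation only (adjusted p = 0.683 with an estimated correlation, exact permutation p = 0.171 for the list mean), lost that call without each of 4 lambs in turn, and KANK3 was the gene that fell. If fewer endothelial cells were the cause, the markers would be lower by similar amounts. Of 15 markers, 13 lay more than 2 standard errors of the difference from KANK3, among them KDR at 0.43 and PECAM1 at -0.31, and the exceptions were CLDN5 at -0.79 and EGFL7 at -0.84, while NOTCH4, an endothelial gene outside these 15, lay near KANK3 at -0.95 and DESeq2 called 2 list members lower over all genes. KANK3 had the smallest p of all tested genes, so its fold change may be overstated and other markers would tend to show smaller ones. The standard errors of the difference also treat genes of the same lambs as independent, and 12 of the 15 markers were lower. The comparison therefore cannot decide whether a loss of endothelial cells was the whole cause of the KANK3 change. A loss of endothelial cells, or of a part of them, that could lower these genes stays open.

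The higher interferon response list rested on few lambs. Without SM20 lamb 4 its mean log2 difference from other genes was 0.25 against 0.60 with it, and its adjusted p by camera was 0.275, so the call may come from that lamb. Whether that lamb had an infection or another condition was not tested.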

How the results depend on the processing

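The 5 genes past the threshold kept their direction under each alternative, and their calls depended on the processing. Genes past the threshold numbered 1 with median-of-ratios scaling, 1 with upper-quartile scaling, 0 without an expression filter, 0 with limma-voom and 0 with 1 surrogate variable. There were 0 with any 1 library left out (range 0 to 0), 446 with DESeq2 and 129 at an adjusted p under 0.10. Chosen after seeing the data, the slow-fibre level as a covariate gave 0. The counts at an unadjusted p under 0.05 lay between 1476 and 1881 over these settings, against 1788. Library size alone, the CPM filter and leaving out the mitochondrially encoded genes each gave 5, voom with sample weights 7 and robust dispersions 6, and library size alone called 3 of the 5 genes. Lists past the threshold numbered 0 with an estimated correlation and 0 by exact permutation of list means, and 5 to 8 under the others. The permutation could hardly pass a list, since its smallest p of 0.0286 passes after adjustment only if most of the 30 lists reach it. C1QB, which was not called, ran from -0.13 to 0.69 with 1 library left out. Mean log2 differences from other genes, none of them called with all 8 libraries, changed sign in the same way: glycolysis -0.0563 to 0.0427, protein breakdown -0.13 to 0.10, heat shock -0.11 to 0.35, immediate early -0.10 to 0.39, endoplasmic reticulum stress -0.19 to 0.00375, circadian -0.21 to 0.0461, extracellular matrix -0.27 to 0.0907, adipocyte -0.29 to 0.0543, macrophage -0.0832 to 0.31, nerve -0.00175 to 0.40 and cell cycle -0.22 to 0.00223. The share of the 10 most abundant genes ran from -1.12 to 0.0941 percentage points. The cause of these changes was not tested, apart from the loss of a library, which leaves 7 lambs. Over the named genes 2075 comparisons with an alternative kept direction and side of the threshold, 64 passed newly, 70 no longer passed and 1 changed sign. Most named genes were not called with all 8 libraries, so most of the 2075 comparisons are of genes that stayed uncalled. The 70 losses all fall on the 5 genes past the threshold, which were each called in 5 to 8 of 20 alternatives. Whether the spread between lambs or the depth limits more what can be called was not compared.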

Other observations

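All tests in this part were chosen after the results were seen. Genes with long messenger RNAs, a group not described above, tended to be higher in SM20: of 45 tested members of a list of long messenger RNAs, 31 had a positive log2 fold change, with a median of 0.30 (exact permutation p of the list mean 0.0571). Of 45 short messenger RNAs from outside mitochondria and ribosomes, 37 were negative, with a median of -0.18 (exact permutation p = 0.0286).

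A hypothesis drawn from this is that transcripts were read by length differently in the 2 diets, as RNA integrity or library preparation might do. The mean of the long list minus that of the short list was higher in SM20 by 0.37 log2 units, and the diets did not overlap (exact permutation p = 0.0286, the smallest 4 lambs against 4 allow). This is consistent with the hypothesis and equally with a response of the muscle, since both lists were chosen with the data in view. Transcript lengths were not tested, as the RefSeq gene table at hand gives the span of each gene with its introns and no transcript lengths. Whether the genes past the threshold, or those nearest it, follow their transcript length was therefore not tested either. The labels give no RNA integrity per lamb.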
